A study of Mus musculus with 9 samples.

How the data were processed

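RNA was measured in 9 libraries of mouse EB5 embryonic stem cells, 3 each of Parental, Zfp352-KO and Zfp352/Zfp353-DKO cells. Per the labels' protocols, total RNA was made into stranded, polyadenylated-RNA libraries (TruSeq) and sequenced on a NextSeq 500 as single-end reads of 75 bases. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, STAR 2.7.8a and RSEM 1.3.3, and the build was mm10. The order and settings of these steps, the release of the gene annotation and whether the counting used the strand are not given in the sources used here. Each deposited table held 24411 gene symbols with RefSeq transcript accessions. Per the file headers, the authors gave an expected count for each gene, an RSEM estimate that divides reads shared between genes and need not be whole, and 9.27% of the values were not whole. The deposited tables also held TPM and FPKM, normalized for transcript length and sequencing depth, per the file headers. TPM was used to show levels, and the FPKM values of the deposited tables were not used.

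Genes were matched to RefSeq genes of GRCm38.p6, the assembly also called mm10, and 24314 of the 24411 symbols matched by symbol or accession. Coordinates are 1-based. GC content came from the transcripts of GENCODE's GRCm38 annotation and was found for 13776 of the 14300 tested genes (96.3%). No row was found for Zfp353, so it was not analysed here. Duplicated or near-identical genes, such as the Tdpoz, Sprr2, Zscan4 and Tcstv families, share reads that the counting had to divide, so values of single members are uncertain, and 39 expression vectors were identical to that of another gene. The list of mitochondrially encoded genes had 0 members in the tables and was left out.

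Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, which ran from 0.992 to 1.01, filterByExpr, glmQLFit and glmQLFTest, two-sided), with all 9 libraries in 1 fit by genotype, 6 residual degrees of freedom and no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with standard errors from the quasi-likelihood F statistic. The common biological coefficient of variation was 4.95%. Depth ran from 16599004 to 22044820 expected counts per library, and the 10 most abundant genes took 5.76% to 5.97% of them. On simulated counts with the real means, dispersions and library sizes, 75% of genes changed 1.5-fold and 89% of genes changed 2-fold were recovered in the comparison of Zfp352-KO with Parental cells (14193 genes, 5 false calls), 75% and 83% in that of Zfp352/Zfp353-DKO with Parental cells (14192 genes, 12 false calls), and 73% and 89% in that of the edited genotypes (14171 genes, 3 false calls).

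Gene lists for cell types, signalling and metabolism that such cultures can show, the tests, the groups and the alternatives were chosen before the data were examined. Of these lists, 24 had at least 3 tested members and were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 72 tests, and again with an estimated correlation and with fry. In a simulated shift of the fibroblast list by -0.4 (14183 genes, Zfp352-KO against Parental), the list was called and 0 other lists were. Genes were drawn independently there, so the simulation could not show false calls from correlated genes. Other splits of the real Zfp352-KO and Parental libraries called up to 11 lists with the preset correlation. The named genes are the targeted genes; in each comparison the 10 largest rises and the 10 largest falls among called genes with a mean TPM of at least 2 in the higher group, no overlap between the libraries in CPM and no clone or predicted-gene name; up to 4 called members of each list with the smallest adjusted p; called genes within 500 kb of a targeted locus; and Pou5f1, Nanog and Sox2. The text gives those among them that bear on a group or kept their calls when any 1 library was left out, and says where a call was lost. Zfp352 was also tested by exact permutation of log2(TPM + 0.1), and its pooled counts by an exact binomial test with a 95% Clopper-Pearson interval. Such intervals, and a floor of 3 counts for genes at 0, cover counting error only.

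The alternatives were other scalings, DESeq2 1.42.0, limma-trend on log2(TPM + 1), other filters and thresholds, a replicate block, fits of the 6 libraries compared and the omission of each library. An alternative chosen after seeing the data removed, in each library, a local regression trend (span 0.3) of log2 CPM on GC content and transcript length, entered as an offset in the same edgeR test. For the fibroblast list, a planned test instead removed a local regression trend (span 0.5) of the log2 fold changes on GC content and length. On 5 sets of simulated libraries with no genotype effect that carried these trends, at most 11 genes were called between Zfp352-KO and Parental without the removal (14300 genes) and at most 2 with it (13776 genes). The dispersions of these sets were those of the real libraries, which already held the trends, so the numbers called may be too low. For the overlap of the comparisons against Parental, 20 sets of unchanged groups were simulated. Other splits of the libraries were refitted, 10 for each comparison and 100 drawn for the overlap.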

Results

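Polyadenylated RNA was sequenced from mouse embryonic stem cells of the EB5 line, a derivative of the male E14tg2a line that is grown without feeder cells in serum and leukemia inhibitory factor. The 9 libraries fell into 3 genotypes with 3 libraries each. Parental cells had neither Zfp352 nor Zfp353 deleted. In Zfp352-KO cells Zfp352 was deleted with CRISPR-Cas9, a guided nuclease that cuts DNA, and in Zfp352/Zfp353-DKO cells both Zfp352 and Zfp353 were. Zfp352 encodes a zinc finger protein known for its transcription in the early embryo. Expected counts summed to between 16599004 (Zfp352-KO library 1) and 22044820 (Zfp352-KO library 2) per library. Counts of libraries within a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 2.50 to 7.06 over the 9 pairs. The labels do not say that libraries of a genotype came from separate cultures or clones, so the p-values measure only the spread between these libraries, which may be technical. On the first principal component (28.0% of the variance of log2 CPM), Parental libraries lay at -22.5, -20.2 and -14.5 and edited libraries between 2.73 and 16.1.

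The libraries also differed in how their values moved with transcript length. Across 13776 genes, Spearman's rho between transcript length and the log2 CPM of a library less the mean of all libraries was -0.308, -0.402 and -0.0797 in Parental libraries 1, 2 and 3. The corresponding values were 0.395, 0.192 and -0.0620 in Zfp352-KO libraries and -0.133, -0.0228 and 0.360 in Zfp352/Zfp353-DKO libraries. These correlations run across genes, which are not independent replicates, and no p-value was attached to them.

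**Figure D1:**
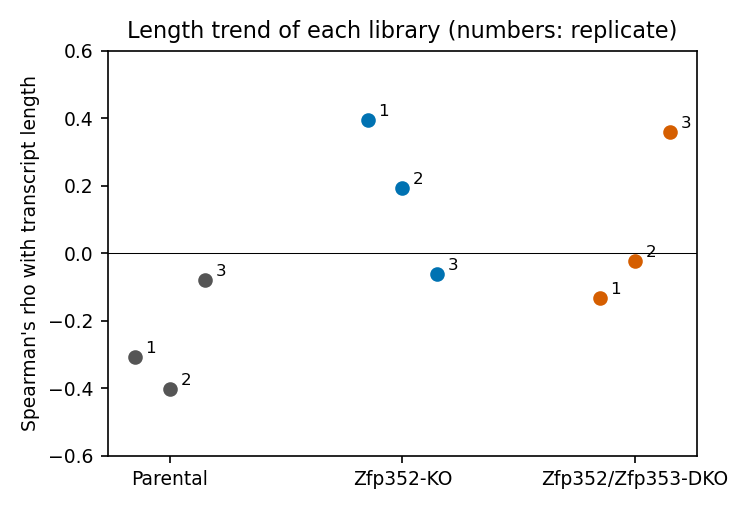
Spearman's rho across 13776 genes between transcript length and each library's log2 CPM relative to the mean of all libraries (y axis), by genotype (x axis), with 1 point per library and its replicate number. Values ran from -0.402 in Parental library 2 to 0.395 in Zfp352-KO library 1, and they also differed among libraries of 1 genotype.

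The targeted gene was read first as a check of the labels. Zfp352 lies on chromosome 4 at 90218820 to 90225687 (GRCm38, the assembly called mm10). It had expected counts of 47, 52 and 41 in the Parental libraries, 3, 8 and 10 in the Zfp352-KO libraries, and 1, 1 and 3 in the Zfp352/Zfp353-DKO libraries. Mean TPM was 1.86 ± 0.162 (SD, n = 3) in Parental, 0.293 ± 0.126 in Zfp352-KO and 0.0733 ± 0.0577 in Zfp352/Zfp353-DKO cells. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Zfp352 fell in Zfp352-KO cells (log2 fold change -2.65 ± 0.32 (SE), adjusted p = 6.1e-05) and in Zfp352/Zfp353-DKO cells (-4.64 ± 0.42, adjusted p = 8.0e-07). A two-sided exact permutation test of log2(TPM + 0.1) gave p = 0.1 for either edited genotype, the smallest that 3 against 3 libraries allow. Summed over libraries, 21 counts remained in Zfp352-KO and 5 in Zfp352/Zfp353-DKO cells, which relative to the summed library totals is a ratio of 4.19 (95% exact interval 1.54 to 14.2, counting error only; two-sided exact binomial p = 0.00249). The edgeR test between the edited genotypes, which takes in the spread between libraries, did not call Zfp352 (log2 fold change -1.99 ± 0.62, adjusted p = 0.45). The locus of Zfp353 is annotated as the pseudogene Zfp353-ps on chromosome 8 at 42081329 to 42083312, and its level was not analysed here. No gene within 500 kb of either locus was among the tested genes.

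**Figure D2:**
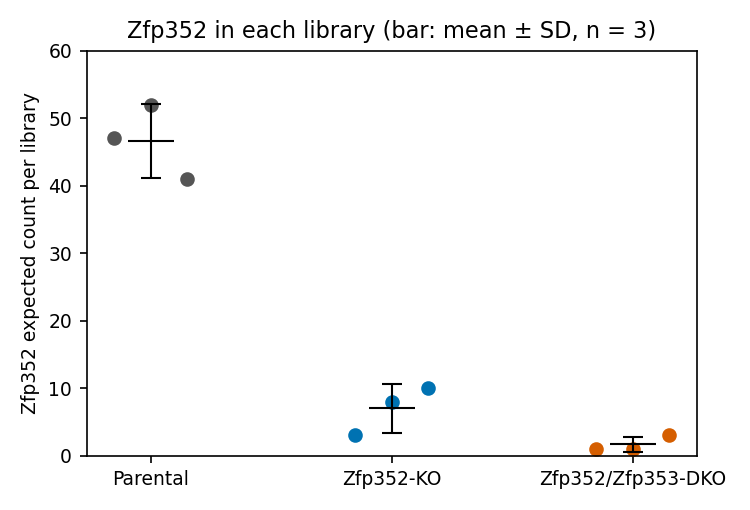
Expected counts of Zfp352 in each library (y axis) by genotype (x axis), with 1 point per library and bars for the mean and SD of 3 libraries. The Parental libraries held 41 to 52 counts, the Zfp352-KO libraries 3 to 10 and the Zfp352/Zfp353-DKO libraries 1 to 3.

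The comparison of Zfp352-KO with Parental cells asked which transcripts differ where Zfp352 alone is deleted. Tdpoz4, a gene of the TD and POZ domain family transcribed in the early embryo, fell by 4.11 ± 0.37 on the log2 scale (SE), from 5.23 ± 0.698 TPM in Parental to 0.293 ± 0.161 TPM in Zfp352-KO cells (SD, n = 3). T, the mesoderm transcription factor Brachyury, fell by 2.65 ± 0.31, and Sprr2a3, which encodes a small proline-rich protein of epithelia, fell by 3.12 ± 0.46. The zinc and manganese transporter gene Slc39a8 (log2 fold change -1.87 ± 0.26), the secreted WNT ligand gene Wnt4 (-1.17 ± 0.19), the caveolae gene Cav1 (-1.32 ± 0.23) and the 2-cell-stage gene Tcstv3 (-1.17 ± 0.16) were lower too. Rises were smaller. Igf2, an imprinted fetal growth factor, rose by 0.70 ± 0.09, Mcf2, a guanine nucleotide exchange factor gene, by 0.69 ± 0.11, Txlnb by 0.71 ± 0.13 and Tmem92 by 0.65 ± 0.09. The adjusted p-values of these 11 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 2.2e-06 for Tdpoz4 to 0.0039 for Txlnb. The pluripotency factors Pou5f1 (-0.09 ± 0.05), Nanog (0.03 ± 0.04) and Sox2 (0.09 ± 0.04) passed no threshold, with adjusted p of 0.29, 0.70 and 0.21 in the same edgeR test.

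Of 14300 tested genes, 490 were higher and 520 lower in Zfp352-KO than in Parental cells, with a median absolute log2 fold change of 0.30 among the calls. Of these, 11 higher and 33 lower genes differed by at least 1 on the log2 scale. Called genes that were higher had a median transcript length of 5789 bases and lower ones of 1874, against 2810 for all genes with a GC value. With the GC content and length trend removed per library, 305 genes were higher and 412 lower, and 489 of 970 calls that could be retested remained. Without Parental library 1 the counts were 50 higher and 160 lower, and without Parental library 2 they were 138 and 244. Without Zfp352-KO library 1 they were 78 and 199, and without Zfp352-KO library 2 they were 150 and 220. As many as 838 genes were higher without Zfp352-KO library 3 and again without Zfp352/Zfp353-DKO library 3. The 11 genes called in the paragraph above kept their direction and side of the threshold in each of these omissions.

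Among gene lists fixed before the data were examined, markers of fibroblast-type cells were lower in Zfp352-KO cells. Of 18 tested markers, 8 fell and none rose (11 fell adjusted over the list alone). Among them were the collagen genes Col1a1 (log2 fold change -1.15 ± 0.09) and Col1a2 (-0.65 ± 0.09), the actin-binding gene Tagln (-0.76 ± 0.07) and the calcium-binding protein gene S100a6 (-0.66 ± 0.08). Camera, a test for shifts of gene lists, gave an adjusted p of 1.8e-16 for the list and of 0.028 with an estimated correlation. Of 18 trophectoderm genes 5 fell and none rose (5 adjusted over the list alone), at a camera adjusted p of 1.4e-06 and of 0.029 with an estimated correlation. The epithelial keratin genes Krt8 (-0.78 ± 0.07), Krt18 (-0.57 ± 0.07) and Krt19 (-0.97 ± 0.08) were among them. The median log2 fold change of the trophectoderm list was -0.04 and its mean -0.27, so the shift lay in part of its genes. Of 11 WNT target genes 5 fell (6 adjusted over the list alone, and 2 by DESeq2), including T, Sp5 (-1.54 ± 0.28) and Cdx2 (-1.27 ± 0.25), with camera adjusted p of 7.9e-06 and of 0.029 with an estimated correlation. Cdx2, a trophectoderm and posterior body transcription factor, was no longer called without Parental library 1 (adjusted p = 0.0541). Primitive streak and mesendoderm genes shared T and Sp5 with that list, and 4 of 11 fell (4 adjusted over the list alone, and 1 by DESeq2; camera adjusted p = 0.00017, and 0.033 with an estimated correlation). DESeq2 gave no adjusted p for T, Sp5 and Cdx2 in this comparison. The median and mean log2 fold change were -0.28 and -0.56 for WNT targets and -0.28 and -0.61 for primitive streak genes, so the largest falls weighed on both means. Neither list was tested without the shared genes, so the calls are not separate findings. Of 22 ERK and immediate early genes 10 fell and none rose (14 fell and 2 rose adjusted over the list alone), at a camera adjusted p of 2.7e-08 and of 0.019 with an estimated correlation. The matricellular genes Cyr61 (-0.78 ± 0.08) and Ctgf (-0.44 ± 0.08) were among the lower ones. At the preset correlation, these 5 lists also kept their calls and directions when any 1 library was left out and when the length and GC trend was removed. The estimated correlation was not applied in those refits.

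The other list calls between Zfp352-KO and Parental cells were lost with an estimated correlation. Naive pluripotency genes shifted up (camera adjusted p = 0.0012, but adjusted p = 0.070 with an estimated correlation). Of 24 genes 5 rose, 7 adjusted over the list alone, including Tfcp2l1 (0.37 ± 0.06) and Tbx3 (0.30 ± 0.05), transcription factors of the naive state. The DNA methylation and silencing list shifted up as well (camera adjusted p = 0.0057, and 0.26 with an estimated correlation; adjusted p = 0.051 without Zfp352-KO library 2). In it 5 of 26 genes were higher, 9 adjusted over the list alone, among them the maintenance methyltransferase gene Dnmt1 (0.45 ± 0.04) and the 5-methylcytosine dioxygenase gene Tet2 (0.47 ± 0.08). Of 27 glycolysis and hypoxia genes 11 fell, 16 adjusted over the list alone, at a camera adjusted p of 5.3e-11 and an adjusted p of 0.26 with an estimated correlation. They included the lactate dehydrogenase gene Ldha (-0.36 ± 0.06) and the lactate transporter gene Slc16a3 (-0.61 ± 0.11). Formative and primed pluripotency genes were lower (5 of 20 lower and 1 higher, the same numbers adjusted over the list alone; camera adjusted p = 0.0057, and 0.066 with an estimated correlation), with Pou3f1 at -0.52 ± 0.08. So were interferon response and MHC class I genes (5 of 24, 10 adjusted over the list alone; 0.00055, and adjusted p = 0.075 with an estimated correlation), with H2-K1 at -0.40 ± 0.07. BMP targets were lower as well (4 of 9, 5 adjusted over the list alone and 2 by DESeq2; 0.0028, and adjusted p = 0.13 with an estimated correlation).

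Cholesterol synthesis genes were called lower (2 of 26 genes lower, 2 adjusted over the list alone; camera adjusted p = 0.0052, and adjusted p = 0.31 with an estimated correlation) with Fdps at -0.28 ± 0.05. Primitive endoderm genes were called lower (5 of 21 lower; 0.0075, and adjusted p = 0.34 with an estimated correlation) with the matrix gene Sparc at -0.32 ± 0.05. Adjusted over the list alone, 5 primitive endoderm genes were lower and 1 higher. That list was not called without Parental library 3 (adjusted p = 0.078), Zfp352-KO library 2 (0.068) or Zfp352-KO library 3 (0.057). NODAL targets were called lower (3 of 9, and 4 lower with 1 higher adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.13 with an estimated correlation), but not without Zfp352-KO library 2 (0.087) or with the length and GC trend removed (0.077). Ribosomal protein genes were called lower (2 of 81, 2 adjusted over the list alone; camera adjusted p = 1.2e-05, and adjusted p = 0.65 with an estimated correlation), and the direction turned to higher with the trend removed (adjusted p = 0.035). One of the 2, Rpl26, had expected counts in steps of 20.36, with 1 to 11 steps per library, and the adjusted p of its lower value by edgeR (0.0011) became 0.063 on the number of steps. The 2-cell-like list was not called (camera adjusted p = 0.084). Its median log2 fold change was 0.19 and its mean -0.04, since Zscan4f (0.36 ± 0.05) and Tmem92 rose while Tdpoz4, Tcstv3 and B020031M17Rik (-1.53 ± 0.18) fell. It passed the threshold upward without Parental library 1 (adjusted p = 0.0497), Parental library 2 (0.0186) or Zfp352-KO library 1 (0.0257) and with the trend removed (0.0346). Lists for neuroectoderm, methylation-silenced germline genes, imprinted genes, p53 targets, histones, the integrated stress response, LIF and STAT3 targets and the Y chromosome were not called, with camera adjusted p from 0.0898 to 0.952. Of these, the integrated stress response list passed the threshold downward without Zfp352-KO library 2 (0.0496), and imprinted genes were tested downward with a median of 0.07.

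**Figure D3:**
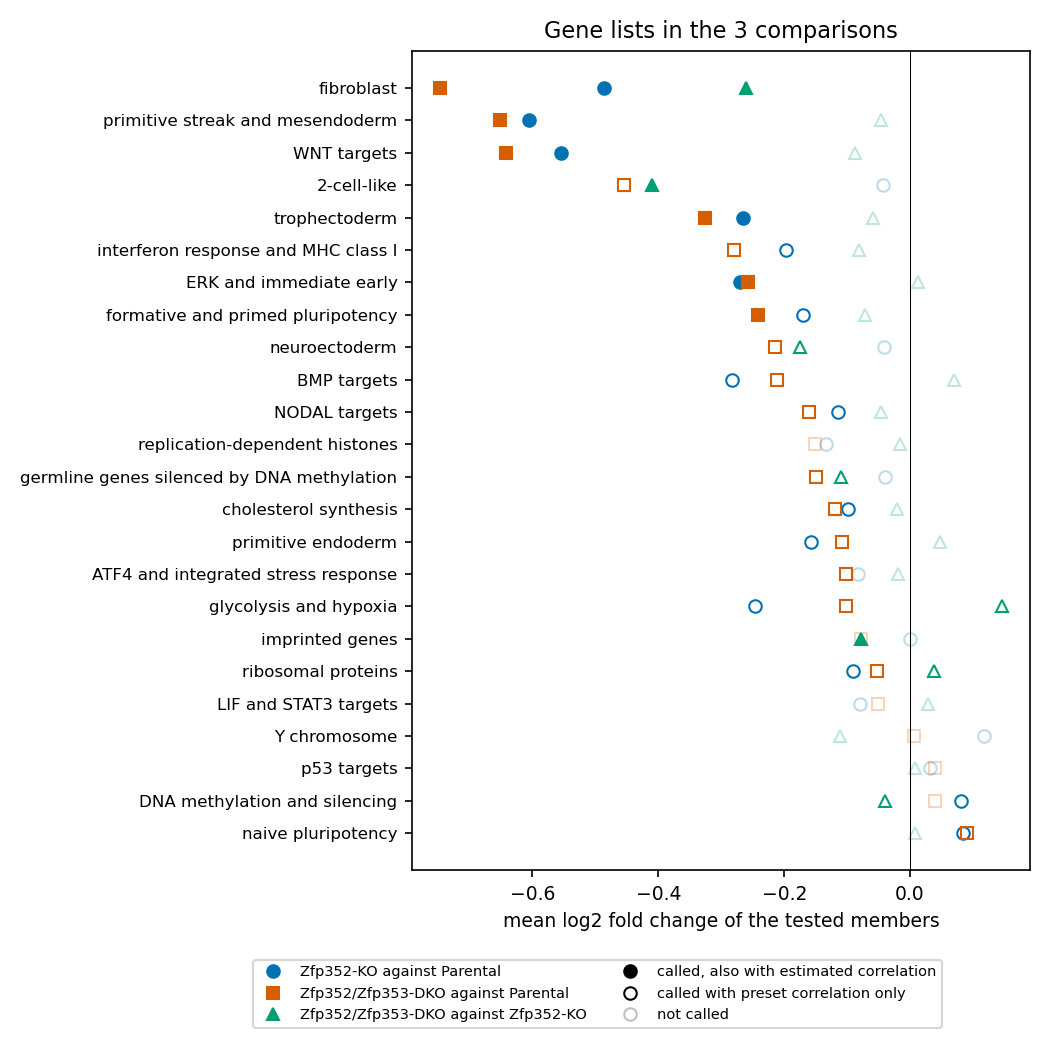
Mean log2 fold change of the tested members (x axis) of each of 24 gene lists (y axis) in the 3 comparisons, with a member at 0 counts in a genotype set to a floor of 3 counts over the group. Filled symbols mark lists called by camera with the preset and the estimated correlation, open symbols lists called with the preset one, and pale symbols lists not called. The fibroblast list lay lowest in the double knockout, at -0.75, and at -0.49 in Zfp352-KO cells against Parental.

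The comparison of Zfp352/Zfp353-DKO with Parental cells asked the same of the deletion of both genes. Tdpoz4 fell by 5.35 ± 0.43 on the log2 scale (SE), T by 3.09 ± 0.33 and Tcstv3 by 1.58 ± 0.17. Slc39a8 (log2 fold change -2.45 ± 0.28) and Wisp1, a WNT-responsive matricellular gene (-1.80 ± 0.16), were lower as well. Sprr2a3 had 86 counts summed over the Parental libraries and 0 in the Zfp352/Zfp353-DKO libraries, at least 27.3-fold lower if 3 counts over the group are taken as the floor. The interferon-inducible GTPase gene Gbp2b (log2 fold change -1.59 ± 0.13) and the protease gene Prss23 (-1.54 ± 0.12) were also lower. Gli1, a transcription factor of Hedgehog signalling, rose by 0.64 ± 0.07, from 12.1 ± 0.924 to 19.3 ± 0.811 TPM (SD, n = 3). Zeb1, a repressor of epithelial genes, rose by 0.67 ± 0.09 and Mcf2 by 0.84 ± 0.10. Adjusted p-values for these genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 1.6e-07 for Prss23 to 5.0e-05 for Zeb1. Sox2 was higher by 0.19 ± 0.04 (edgeR adjusted p = 0.011), whereas Pou5f1 (-0.07 ± 0.05, adjusted p = 0.41) and Nanog (-0.02 ± 0.04, adjusted p = 0.81) passed no threshold.

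In this comparison 522 genes were higher and 689 lower, 9 and 103 of them by at least 1 on the log2 scale, and with the length and GC trend removed 507 were higher and 838 lower. Without Parental library 1 the counts were 123 higher and 326 lower, without Parental library 2 they were 222 and 427. Without Zfp352/Zfp353-DKO library 2 they were 258 and 388, and without Zfp352/Zfp353-DKO library 3 224 were higher.

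Fibroblast-type markers were again lower: 10 of 18 fell and none rose (12 fell adjusted over the list alone), at a camera adjusted p of 1.3e-32 and of 0.019 with an estimated correlation. Col1a1 was at -1.66 ± 0.09, Col1a2 at -1.27 ± 0.09, Tagln at -1.25 ± 0.08 and Col5a1 at -0.81 ± 0.07. Trophectoderm genes (5 of 18 lower, 5 adjusted over the list alone; camera adjusted p = 4.5e-08, and 0.028 with an estimated correlation) included Krt18 at -0.82 ± 0.07, Krt19 at -1.06 ± 0.08 and Cdx2 at -1.69 ± 0.27. The median of that list was -0.09 and its mean -0.33, so here too the shift lay in part of its genes. WNT targets (5 of 11 lower, 5 adjusted over the list alone; 9.9e-05, and 0.033 with an estimated correlation) included Sp5 at -1.79 ± 0.29. Primitive streak genes (3 of 11, 4 adjusted over the list alone; 0.00034, and 0.033 with an estimated correlation) included T and the mesoderm factor gene Hand1 at -0.70 ± 0.12. The median and mean were -0.29 and -0.64 for WNT targets and -0.44 and -0.65 for primitive streak genes, which share members. ERK and immediate early genes (9 of 22 lower and 2 higher, 11 and 2 adjusted over the list alone; 8.9e-08, and 0.019 with an estimated correlation) included Cyr61 at -1.06 ± 0.08. In that list Spry4, a feedback inhibitor of ERK signalling, was higher by 0.23 ± 0.04. Formative and primed pluripotency genes (7 of 20 lower and 1 higher, 8 and 2 adjusted over the list alone; 0.00058, and 0.033 with an estimated correlation) included Pou3f1 at -0.66 ± 0.08 and the neural cadherin gene Cdh2 at -0.50 ± 0.08.

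The remaining list calls of the double knockout against Parental were lost with an estimated correlation. Naive pluripotency genes shifted up (8 of 24 higher and 2 lower, 10 and 3 adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.070 with an estimated correlation), with Tfcp2l1 at 0.37 ± 0.06 and Tcl1 at 0.36 ± 0.06. Dppa3, a maternal factor gene, fell by 0.34 ± 0.06. The 2-cell-like list shifted down (7 of 32 lower and 2 higher, 9 and 4 adjusted over the list alone; 0.0022, and adjusted p = 0.26 with an estimated correlation) with Sp110 at -1.23 ± 0.13, and stayed called without Gm4340, at 0 counts in the double knockout (adjusted p = 0.0041). Interferon response and MHC class I genes (8 of 24 lower, 12 lower and 1 higher adjusted over the list alone; 7.7e-05, and adjusted p = 0.063 with an estimated correlation) included the immunoproteasome gene Psmb8 at -1.07 ± 0.19. Methylation-silenced germline genes (5 of 27 lower, 2 by DESeq2, 7 lower and 1 higher adjusted over the list alone; 0.015, and adjusted p = 0.13 with an estimated correlation) included Stk31 at -0.53 ± 0.08. Cholesterol synthesis genes (4 of 26 lower, 7 adjusted over the list alone; 0.0015, and adjusted p = 0.26 with an estimated correlation) included Fdps at -0.34 ± 0.05. Primitive endoderm genes (7 of 21 lower and 2 higher, the same adjusted over the list alone; 0.0066, and adjusted p = 0.33 with an estimated correlation) included Sparc at -0.46 ± 0.05. The list was not called without Parental library 3 (adjusted p = 0.085). NODAL targets (3 of 9 lower, 4 adjusted over the list alone; 0.022, and adjusted p = 0.13 with an estimated correlation) were lower as a list. The list missed the threshold with the length and GC trend removed (adjusted p = 0.053).

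The 5 other downward list calls of the double knockout also depended on single libraries. BMP targets (2 of 9 lower, 1 by DESeq2, 4 adjusted over the list alone; camera adjusted p = 0.030, and adjusted p = 0.26 with an estimated correlation) were not called without Parental library 3 (0.075), without Zfp352/Zfp353-DKO library 3 (0.089) or with the trend removed (0.096). Glycolysis and hypoxia genes (2 of 27 lower, 1 by DESeq2, 7 adjusted over the list alone; 0.017, and adjusted p = 0.71 with an estimated correlation) were not called without Parental library 1 (0.11), without Zfp352/Zfp353-DKO library 2 (0.32) or with the trend removed (0.061). Ribosomal protein genes (1 of 81 lower, 0 adjusted over the list alone; 0.010, and adjusted p = 0.79 with an estimated correlation) were not called without Parental library 2 (0.51) or Zfp352/Zfp353-DKO library 3 (0.74), and were higher with the trend removed (0.021). Neuroectoderm genes (3 of 11 lower, 4 lower and 1 higher adjusted over the list alone; 0.046, and adjusted p = 0.26 with an estimated correlation) include the intermediate filament gene Nes at -0.70 ± 0.06. That list was not called without Parental library 1 (0.068), Parental library 2 (0.079), Zfp352-KO library 2 (0.053), Zfp352-KO library 3 (0.051), Zfp352/Zfp353-DKO library 1 (0.10) or Zfp352/Zfp353-DKO library 3 (0.086). The integrated stress response list (4 of 28 lower and 1 higher, 5 and 2 adjusted over the list alone; 0.0498, and adjusted p = 0.51 with an estimated correlation) includes the stress-induced transcription factor gene Atf3 at -1.15 ± 0.18. It was not called without Parental library 2 (0.15), Parental library 3 (0.072), Zfp352-KO library 1 (0.053), Zfp352-KO library 2 (0.065), Zfp352-KO library 3 (0.065) or Zfp352/Zfp353-DKO library 3 (0.23), nor with the trend removed (0.49). Imprinted genes, p53 targets, histones, LIF and STAT3 targets, the Y chromosome and the DNA methylation list were not called (camera adjusted p from 0.0799 to 0.629), although Dnmt1 was higher by 0.44 ± 0.04. Imprinted genes passed the threshold downward by fry (adjusted p = 0.0043) and, by camera, without Parental library 2 (0.045) and with the trend removed (0.019).

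**Figure D4:**
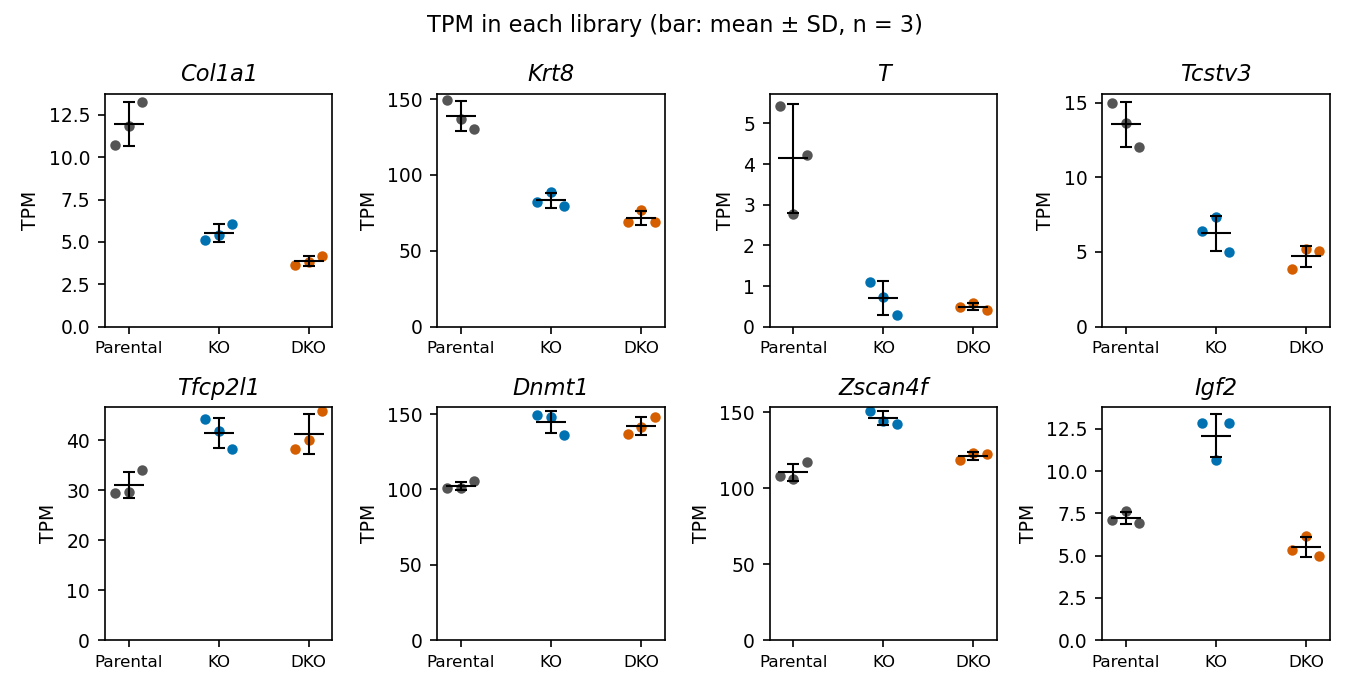
TPM of 8 genes (y axes, each from 0) in the 3 Parental, 3 Zfp352-KO and 3 Zfp352/Zfp353-DKO libraries (x axes), with 1 point per library and bars for the mean and SD. Col1a1 fell from 11.9 TPM in Parental to 5.53 and 3.87 TPM in the edited genotypes, while Igf2 was 7.23, 12.1 and 5.50 TPM.

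Both comparisons used the same Parental libraries, and their calls overlapped. Of the called genes, 250 were higher in both edited genotypes and 346 lower in both. These 596 were 59.0% of the calls of Zfp352-KO and 49.2% of those of Zfp352/Zfp353-DKO, and with the length and GC trend removed 501 were called alike. Independent lists of these sizes would share 17.9 higher and 25.1 lower genes, a number that takes no account of shared controls. In 20 simulations of unchanged groups against shared controls, at most 1 gene was called alike. Unchanged groups have few calls to share, so this cannot show what shared controls add to the overlap of changed groups. Col1a1, Krt8, Krt19, T, Sp5, Tdpoz4 and Tcstv3 were among the genes lower in both, and Tfcp2l1, Tbx3, Tet2, Dnmt1 and Mcf2 among those higher in both. A single gene, Igf2, named here after its values were seen, was called in opposite directions. It was higher in Zfp352-KO cells (0.70 ± 0.09) and lower in Zfp352/Zfp353-DKO cells (-0.43 ± 0.10, edgeR adjusted p = 0.014). The lower call of Igf2 was not followed through the omissions of single libraries. The covariance of the fold changes over all tested genes was 0.0562 against 0.0147 on average (at most 0.0158) in the simulations, and the correlation was 0.680 against 0.494. The Parental libraries are too few to be split into parts of at least 2, so part of the excess may come from the shared controls. The number called alike was 162 without Parental library 1, 273 without Parental library 2, 236 without Zfp352-KO library 1, 299 without Zfp352-KO library 2 and 358 without Zfp352/Zfp353-DKO library 2.

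**Figure D5:**
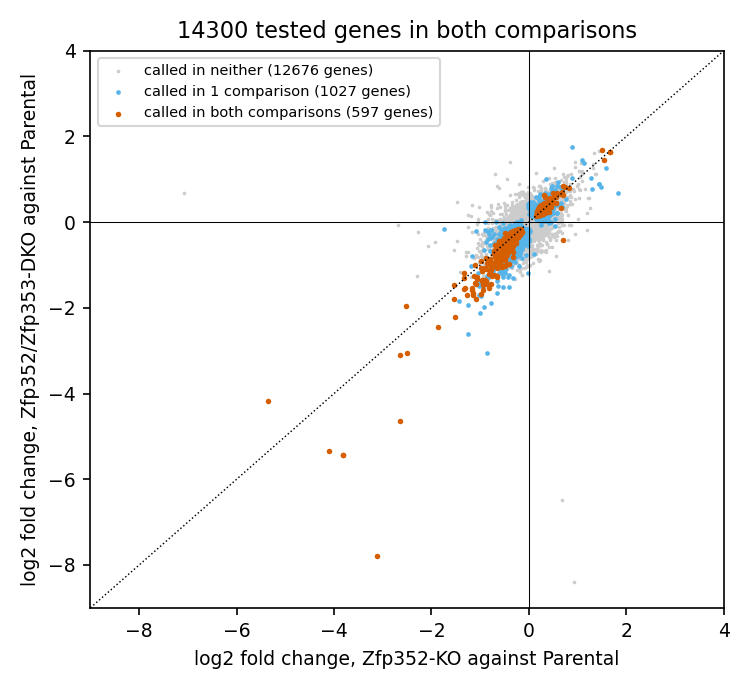
Log2 fold change of each of 14300 tested genes in Zfp352/Zfp353-DKO (y axis) against that in Zfp352-KO (x axis), both against Parental. Colours mark genes called in neither, in 1 or in both comparisons, and a dotted line marks equal change. The 596 genes called alike lie in the upper right (250) and lower left (346).

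The comparison of Zfp352/Zfp353-DKO with Zfp352-KO cells asked what differs when Zfp353 is deleted in addition. The edited genotypes may be separate lines, so a difference between lines cannot be told apart from the loss of Zfp353. Igf2 was lower in the double knockout (log2 fold change -1.13 ± 0.10 (SE); 5.50 ± 0.608 against 12.1 ± 1.26 TPM, SD, n = 3), as were Thbs1, the gene of the matrix protein thrombospondin (-0.62 ± 0.07), and Calcoco2, an autophagy receptor gene (-0.43 ± 0.06). Their adjusted p were 7.0e-06, 0.00022 and 0.0025 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These 3 genes kept their calls whichever library was left out, with adjusted p of at most 0.00014, 0.0041 and 0.042. In all, 13 genes were lower and 2 higher. The contractile and matrix genes Col1a2 (-0.62 ± 0.10), Acta2 (-0.56 ± 0.10), Tagln (-0.49 ± 0.08) and Flnc (-0.40 ± 0.07), and Prss23, Adgra3, Nes, Stk31 and Zscan4f, were among the lower ones. The axon guidance gene Ntn1 was higher (0.43 ± 0.07). Rpl26 was the other higher call, with an adjusted p by edgeR that went from 0.034 to 0.59 when its count steps of 20.36 were taken as the unit. Each of these 11 genes lost its call when some libraries were left out, at adjusted p of up to 0.13 for Col1a2, Tagln and Ntn1 and up to 0.25 for Stk31. The lower calls numbered 5 without Parental library 1, 8 without Parental library 2 or Zfp352-KO library 1, 5 without Zfp352-KO library 2, 4 without Zfp352-KO library 3 and 3 without Zfp352/Zfp353-DKO library 1 or 2. The higher calls numbered 1 without Parental library 3, Zfp352-KO library 1 or 2 or Zfp352/Zfp353-DKO library 2, 0 without Zfp352-KO library 3 or Zfp352/Zfp353-DKO library 1, and 8 without Zfp352/Zfp353-DKO library 3. With the length and GC trend removed, 50 genes were lower and 7 higher, and all 15 calls remained.

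Between the edited genotypes, 3 lists were called with either correlation. The 2-cell-like list was lower in the double knockout (median log2 fold change -0.22; camera adjusted p = 1.6e-18, and 0.028 with an estimated correlation), with 1 of 32 genes called lower, Zscan4f (-0.26 ± 0.05), 2 by DESeq2, and 14 lower adjusted over the list alone. Without Gm4340, a member with 0 counts in the Zfp352/Zfp353-DKO libraries that was left out after its values were seen, the camera adjusted p was 2.9e-17, and 0.028 with an estimated correlation. Fibroblast-type markers were lower (3 of 18, 6 by DESeq2, and 8 lower with 1 higher adjusted over the list alone; 5.8e-13, and 0.033 with an estimated correlation). Imprinted genes were lower too (1 of 36, Igf2, 1 lower and 1 higher by DESeq2, and 2 lower with 1 higher adjusted over the list alone; 0.0022, and 0.040 with an estimated correlation), with a median log2 fold change of -0.03. Without Igf2, in a test chosen after its values were seen, the 35 other imprinted genes were not called (adjusted p = 0.088, and 0.19 with an estimated correlation). At the preset correlation, these 3 lists kept their calls when any 1 library was left out and with the length and GC trend removed. The estimated correlation was not applied in those refits. Methylation-silenced germline genes (1 of 27 lower, 1 adjusted over the list alone; 0.0016, and adjusted p = 0.064 with an estimated correlation) were lower. Glycolysis and hypoxia genes were higher as a list with 0 of 27 genes called by edgeR, 0 by DESeq2, 0 adjusted over the list alone and 8 higher at an unadjusted p under 0.05 (camera adjusted p = 2.3e-10, and adjusted p = 0.27 with an estimated correlation).

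The 3 remaining list calls between the edited genotypes changed with single libraries. Neuroectoderm genes (1 of 11 lower, 1 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation) were not called without Zfp352-KO library 3 (0.089), without Zfp352/Zfp353-DKO library 3 (0.16) or with the trend removed (0.062). The DNA methylation and silencing list (0 of 26 genes called by edgeR or DESeq2, 0 adjusted over the list alone, 2 lower at an unadjusted p under 0.05; camera adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation) was not called lower without Zfp352-KO library 1 (0.087), Zfp352-KO library 2 (0.32) or Zfp352/Zfp353-DKO library 1 (0.13). Ribosomal protein genes (1 of 81 higher, 0 by DESeq2, 1 adjusted over the list alone; 0.013, and adjusted p = 0.79 with an estimated correlation) were not called without Zfp352-KO library 1 (0.55) or Zfp352/Zfp353-DKO library 1 (0.67), where the direction turned, nor without Zfp352/Zfp353-DKO library 2 (0.30) or with the trend removed (0.49). The other 16 lists were not called, at camera adjusted p from 0.107 to 0.813. Among them, trophectoderm genes passed the threshold downward without Zfp352-KO library 2 (0.0486), and interferon response genes without Zfp352-KO library 1 (0.023) or Zfp352/Zfp353-DKO library 1 (0.043). The Y chromosome list did so without Zfp352/Zfp353-DKO library 3 (0.024). With the trend removed, formative and primed pluripotency genes (0.041) and trophectoderm genes (0.045) were called lower. WNT targets were tested upward with a median of -0.02 and a mean of -0.09, NODAL targets downward with a median of 0.03, and primitive endoderm genes downward with a median of 0.02.

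No chromosome was called in any comparison. Among the autosomes and X, 20 chromosomes, the largest shift of a chromosome's median log2 fold change from that of all genes was 0.033 (chromosome 18, Zfp352-KO against Parental), where 3 copies in place of 2 would give 0.585. The Y chromosome, with 8 tested genes, lay at 0.117 in Zfp352-KO and 0.0398 in Zfp352/Zfp353-DKO cells against Parental and at -0.0436 between the edited genotypes. The smallest camera adjusted p was 0.992, and 0.946 with an estimated correlation.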

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

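The removal of the GC content and length trend was chosen after seeing the data; the other alternatives were planned. Of 201 named results, 105 kept direction and side of the threshold in all of up to 20 alternatives, 92 lost a call in at least 1 and 4 changed sign, none of them called. For genes higher and lower in Zfp352-KO than in Parental (490 and 520), limma-trend gave 122 and 237, an adjusted p under 0.01 gave 73 and 184, an absolute log2 fold change of at least 1 gave 11 and 33, no filter gave 843 higher, the 6 libraries alone 759 higher and the trend's removal 305 higher. For Zfp352/Zfp353-DKO against Parental (522 and 689), these were 193 and 385, 134 and 333, 9 and 103, and 800 higher without a filter. Between the edited genotypes (2 higher and 13 lower), DESeq2 gave 5 and 22, limma-trend 0 and 1, no filter 22 and 44, the 0.01 threshold 0 and 3, the log2 threshold 1 and 1, the 6 libraries alone 0 and 3, and the trend's removal 7 and 50. The overlap (596) was 224 with limma-trend, 906 without a filter, 191 at 0.01 and 32 at the log2 threshold. Whether replicate numbers paired the libraries stayed open. Same-numbered residuals correlated at -0.0767 to 0.106, above 0.1 in 1 of 9 pairs, but 6 of 9 libraries correlated best with their own number. With the replicate number as a block, calls were 232 higher and 337 lower for Zfp352-KO, 333 higher for the double knockout and 8 lower between the edited genotypes, and the overlap 367. List calls with an estimated correlation were 5 of 15, 6 of 18 and 3 of 8 in the 3 comparisons, and fry gave 4 in the last. Leaving out 1 library gave 50 to 838 higher and 160 to 714 lower genes for Zfp352-KO, 123 to 697 and 326 to 726 for the double knockout, 0 to 8 and 3 to 14 between the edited genotypes, an overlap of 162 to 716, and 13 to 16, 14 to 17 and 7 to 8 lists. Reversed signs were those of Nanog in the double knockout against Parental (0.01029 with limma-trend, 0.003972 without Parental library 2, 0.003889 without Zfp352/Zfp353-DKO library 1; -0.036 to 0.003972 over all omissions) and of Pou5f1 (0.01937 and 0.01683 against Parental with the trend removed in Zfp352-KO and the double knockout; between the edited genotypes -0.002533 with the trend removed, -0.01684 without Zfp352-KO library 1, -0.01763 without Zfp352/Zfp353-DKO library 1, -0.01763 to 0.06579 over all omissions). Stricter thresholds call fewer genes by construction; the cause of the other differences was not tested. DESeq2 gave no adjusted p for 3050, 278 and 1387 genes, among them, in Zfp352-KO against Parental, Zfp352, Tdpoz4, Sprr2a3, T, Slc39a8, Cav1, Wnt4, Sp5, Cdx2 and B020031M17Rik. Depth limits the values of genes near 0 counts, such as Zfp352 (1 to 52 per library) and Sprr2a3.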

Other observations

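Of the tests in this part, those chosen only after the result was seen were those of the share of the fall over fibroblast-type markers, of the shared Parental libraries, of the length trend (with the refit of a split of the edited libraries), of a difference of the Parental culture, and of the count steps of Rpl26.

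Among single genes, picked after their values were seen and not tested as a group, 3 were lower in both edited genotypes: the collagen IV genes Col4a1 (log2 fold change -0.50 ± 0.08 (SE) in Zfp352-KO, -0.49 ± 0.08 in Zfp352/Zfp353-DKO) and Col4a2 (-0.53 ± 0.09 and -0.61 ± 0.09), and Serpinh1, the collagen chaperone gene (-0.35 ± 0.06 and -0.49 ± 0.06). Zscan4f, which marks the transient 2-cell-like state, went the other way from Tdpoz4 and Tcstv3 in Zfp352-KO cells. It rose from 110 ± 5.71 to 146 ± 4.57 TPM (SD, n = 3) and stood at 121 ± 2.55 TPM in the double knockout. H19, the imprinted neighbour of Igf2, fell in Zfp352-KO cells (-0.38 ± 0.06), where Igf2 rose. In the double knockout, where Igf2 was lower than in Parental cells, 0 of 36 tested imprinted genes were called higher. An opposite change of H19 was thus not called there. Summed over copies, the 5 Tdpoz genes stood at log2 fold changes of -1.86 ± 0.21 and -1.74 ± 0.21 against Parental in Zfp352-KO and in the double knockout, and the 12 Sprr2 genes at -3.54 ± 0.27 and -5.18 ± 0.33. Their adjusted p was at most 3.5e-05 by edgeR, so a division of reads among these named copies alone would not give the lower values. Copies under other names were outside the sums, and Zscan4 and Tcstv copies were not summed. The Tdpoz sum fell less than Tdpoz4 alone and was not called between the edited genotypes (0.12 ± 0.26, edgeR adjusted p = 0.98). The sum therefore does not bear out the size of the fall of Tdpoz4. Of the 75-base windows of the Zfp352 transcript, 23.9% lie in Zfp353-ps with at most 2 mismatches and 63 of 2202 without any, which leaves reads from the Zfp353 locus as a possible source of the residual Zfp352 counts of Zfp352-KO cells. The counts of Rpl26 moved in steps of 20.36, so its calls rest on 1 to 11 such steps per library.

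The first pattern is the lower fibroblast-type markers in both edited genotypes. A smaller share of 1 contaminating or differentiated cell type with a fixed profile would lower all its transcripts by the same share, and the share of the double knockout's fall that Zfp352-KO cells reached was 0.804 for Col1a1, 0.611 for Vim, 0.505 for Acta2 and 0.389 for Col3a1, and, at the extremes, 4.50 for Thy1 and -0.538 for Fbn1. Thy1 stood at 5.91 ± 0.38 CPM (SE) in Parental and 5.46 ± 0.36 in the double knockout, so its share rests on a fall within its error. The shares differed over the tested markers (n = 18), their errors taken as independent, by more than their error (parametric bootstrap p = 0.0001 from 10000 simulated sets, the smallest they can give, and at most 0.003 from 1000 sets each with any 1 marker left out, Thy1 in that case). These errors held only the spread between libraries. The length trend was not removed, and its mean rho was 0.175 in Zfp352-KO and 0.0681 in the double knockout. Differences between lines or that trend could also make the shares differ, so the test cannot decide whether such a cell type was the whole cause. Length or GC bias fell short as the whole cause of the lower list. The list's median in the double knockout went from -0.67 to -0.59 when a trend of the fold changes themselves on GC content and length was removed. Random lists had an interquartile range of 0.0459. A smaller share of 1 cell type, lower transcription of these genes within the stem cells, or a change in more than 1 differentiated cell type stays open as a hypothesis. Which cells the marker transcripts came from was not tested.

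The second pattern is the 596 genes changed alike in both edited genotypes. In simulations with genes drawn independently, the spread of the shared Parental libraries gave a covariance of the fold changes of up to 0.0158, and 0.0562 was found. With the length and GC trend removed, the covariance was still 0.0354 above the mean of these simulations. That mean came from 14300 genes without the removal, in place of 13776. Such independent spread therefore fell short as the whole cause, also with the trend removed. A shift common to the Parental libraries could not enter the simulations, so they cannot exclude the shared controls. Loss of Zfp352, which both edited genotypes share, is a candidate explanation. A difference of the Parental culture, or a common ancestor of both edited lines, cannot be told apart from it, because there is 1 Parental line and the 15 genes called between the edited genotypes would be few under either. Of 100 splits of the 9 libraries into 3 groups of 3, the real one included, 1 gave as many genes called alike. The highest other split gave 431 and kept the Parental libraries together. The splits therefore show mainly that the Parental libraries differed from the edited ones. They cannot exclude chance differences between lines or cultures.

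The third pattern is that longer transcripts were higher and shorter ones lower in Zfp352-KO cells (Spearman's rho 0.381 across 13776 genes, and -0.361 with GC content, which was not separated from length). A trend that differs between libraries of 1 genotype, such as RNA integrity or library preparation could give, stays possible. The rho with length ranged over 0.492 among the Zfp352/Zfp353-DKO libraries, more than the difference of 0.438 between the Zfp352-KO and Parental means. It ranged over 0.457 among Zfp352-KO and 0.322 among Parental libraries, whose values were all negative. A range of single libraries varies more than a difference of means of 3, so these values cannot decide whether such a trend gave that difference. With the length and GC trend removed, 489 of 970 calls remained and 228 were new. The other 481 ended, at a median absolute log2 fold change of 0.11 in place of 0.25 (median SE 0.05 and 0.07). Simulated libraries with these trends and no genotype effect gave at most 11 calls. Their spread was taken from the real libraries and already held the trend, so that number may be too low and decides nothing here. How many calls the trend made is open, as is an effect of Zfp352 on long transcripts. Zfp352-KO libraries 1 and 2 and Zfp352/Zfp353-DKO library 3, whose rho was above 0, form the split of the edited libraries that called 215 genes where the real split called 15. Of the 215 genes, 203 had a GC value and could be retested. With the trend removed, that split called 0 genes by edgeR, so its calls point to this structure of the samples.

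With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Between Zfp352-KO and Parental, the real split called 1010 genes and 15 lists, as many as 1 of the 10 splits each, and the highest other split 0 genes and 11 lists. Between Zfp352/Zfp353-DKO and Parental, the real split called 1211 genes and 18 lists (1 of 10 splits each) and the highest other split 1 gene and 8 lists. Between the edited genotypes, 2 of 10 splits called at least 15 genes, with 215 in the highest other, and 1 of 10 called 8 lists, with 7 in the highest other.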
